A study of Mus musculus with 24 samples.

How the data were processed

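Total RNA of dissected mouse forelimb and hindlimb buds (strain C57/Bl6 per the labels) was sequenced by the authors from stranded libraries, 1 library per sample. Groups were taken from the labels: stage (E10.5, E11.5), limb and genotype, where U11 floxed embryos without Prrx1-Cre are called WT and those with it mutant. All 24 libraries were placed in 8 groups of 3, and none was left out of the fits described first. The deposited values are TPM per gene symbol, scaled by the authors to 1000000 in each library, which was checked on every library. Alignment used HISAT2 on mm10 according to the submitters' processing notes; the quantifier, the annotation and the strand counted are not given in the sources used here. Per the labels, reads of E10.5 libraries were trimmed by 3 nt, those of E11.5 were not, so the stages were fitted apart and stage comparisons carry that difference. TPM keeps no read depth, so the precision of low values is unknown. Gene coordinates and types were taken from GENCODE M21 (GRCm38), which matched 36217 of 38019 symbols; 21018 were nuclear protein-coding.

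TPM values were transformed as log2(TPM + 1), genes with at least 1 TPM in at least 3 libraries of a fit were kept, and limma 3.58.1 (R 4.3.3) with an intensity trend was fitted to the 12 libraries of a stage (8 residual degrees of freedom), or to all 24 for comparisons between stages. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were mutant with WT in each limb and stage, the difference of that effect between limbs and between stages, HL with FL within each genotype and stage, and E11.5 with E10.5 in WT. Rnu11 was also compared by exact two-sided permutation tests of 3 against 3. After the deposited scale was seen to shift most genes, fold changes in the text were taken from fits in which each library was rescaled so that the median log2 value over genes with at least 5 TPM in every library was equal (4168 genes at E10.5, 3949 at E11.5, 3518 over all 24); counts are given on both scales.

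Gene lists were tested by camera with its preset correlation of 0.01, and again with an estimated correlation, where at least 5 members were tested, with Benjamini-Hochberg adjustment over the lists of a comparison. There were 27 lists, 24 written by hand from general knowledge and 3 by symbol pattern. The lists cover the spliceosomes, minor introns, p53, stress, cell cycle, limb patterning, cell types and housekeeping classes. The minor-intron list was written by hand because no genome sequence was used here; a scan for minor splice sites was therefore not run, and splicing itself was not analysed here. Gene lists, comparisons, tests, the naming rule and most alternatives were chosen before the data were examined.

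Named genes are Rnu11; the 6 largest rises and 6 largest falls past the threshold with no overlap between groups and a mean of at least 5 TPM in the higher group, without predicted genes, Xist or Y-linked genes; up to 3 passing members of each list by adjusted p, or the 2 highest members where none passed; and all limb identity genes in HL against FL. For differences between effects and between stages, the 3 largest in each direction and passing list members were named. Further names are marked in the text as chosen after values were seen, and members given as values for lists without calls are examples.

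Whether libraries of equal replicate number were related was checked by correlating their residuals. FL and HL of E10.5 mutants met the criterion of a correlation over 0.1 in each of 3 pairs (0.163 to 0.32), and other groups did not. The Xist-positive mutant libraries bore equal numbers in FL and HL at both stages (1 and 3 at E10.5, 3 at E11.5). Embryos shared between limbs at E11.5 are thus not excluded. Alternatives were a pseudocount of 0.1, no filter, rescaling, only the 6 compared libraries, all 24 libraries, the replicate number as a block, and each library left out in turn. Added after seeing the data were nuclear protein-coding genes only, summed anew, the removal of libraries with Xist at 5 TPM or more (leaving 1 mutant library in each E10.5 limb, whose spread is then taken from the other groups), combinations of rescaling with the other settings, and leave-outs with the genes of the full fit kept, for named genes that otherwise fell under the filter. The procedure was tested on simulated data with 200 changed genes, all with a mean above about 5 TPM. Noise was drawn apart for each gene and library. The rates that follow need not hold for lower genes or where libraries differ as a whole. In the E11.5 FL layout it recovered 88% of 2-fold and 97% of 4-fold changes with 8 false calls, and in the E10.5 FL layout 74% and 96% with 5. A simulated shift of 0.4 log2 in 1 group gave 6433 and 2365 false calls on the unscaled values, and 16 and 8 after rescaling. Correlations between replicates were 0.945 to 0.991 over 24 pairs, and no pair was identical. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.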

Results

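The data are total RNA sequencing profiles of mouse limb buds in which Rnu11, the gene for the U11 small nuclear RNA of the minor spliceosome, carries floxed alleles. Prrx1-Cre, which is active in limb mesenchyme, was absent (WT) or present (mutant). There are 24 libraries in 8 groups of 3: forelimb (FL) and hindlimb (HL), at embryonic stages E10.5 and E11.5, WT and mutant. Read depth is unknown, since TPM values keep no depth, so low values carry an unstated counting error. The labels do not say which embryos the libraries came from, so each p measures the spread between these libraries. Unless stated otherwise, gene changes are log2 fold changes of TPM + 1 (differences of mean log2 values), mutant against WT, after each library was rescaled to a common median, with the standard error of the limma fit (two-sided, Benjamini-Hochberg adjusted). For genes at low levels the added 1 makes them smaller than the ratio of the levels printed beside them. Levels are rescaled TPM, mean with SD over the 3 libraries of a group.

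The first question was whether Rnu11 was lowered in each library labelled mutant. Rnu11 was 242.5, 842.3 and 1124 TPM in the E10.5 FL WT libraries and 141.6, 121.2 and 343.5 TPM in the mutant ones. In E10.5 HL it was 1047, 628.8 and 556.3 against 304.9, 279.5 and 253.1 TPM. At E11.5 it was 1163, 870.0 and 982.5 against 219.8, 183.6 and 164.8 TPM in FL, and 1385, 1528 and 818.7 against 310.3, 302.4 and 291.6 TPM in HL. The library labelled E10.5 FL WT replicate 1 lay below the library labelled E10.5 FL mutant replicate 3. The mutant mean was 27.5% of WT in E10.5 FL, 37.5% in E10.5 HL, 18.8% in E11.5 FL and 24.2% in E11.5 HL. Exact two-sided permutation tests gave p = 0.2 for E10.5 FL and 0.1 for each of the other groups, 0.1 being the smallest p that 3 against 3 libraries allow. In the limma fits Rnu11 fell in E11.5 FL (-2.91 ± 0.27, adjusted p = 0.000702). The other values were -1.92 ± 0.27 in E11.5 HL (0.0634, but 0.000938 on the deposited scale), -1.59 ± 0.58 in E10.5 FL (0.873) and -1.47 ± 0.58 in E10.5 HL (1). Rnu11 lies on chromosome 4 at 132270080 to 132270213, on the minus strand (GRCm38). Gm28872, on the opposite strand at 132270056 to 132270213, covers all of it, and the strand used for counting is not given, so reads of the pair cannot be told apart by symbol. Rnu12, the U12 RNA gene, ranged from 221.4 to 931.7 TPM at E10.5 and from 7.81 to 33.0 TPM at E11.5.

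**Figure D1:**
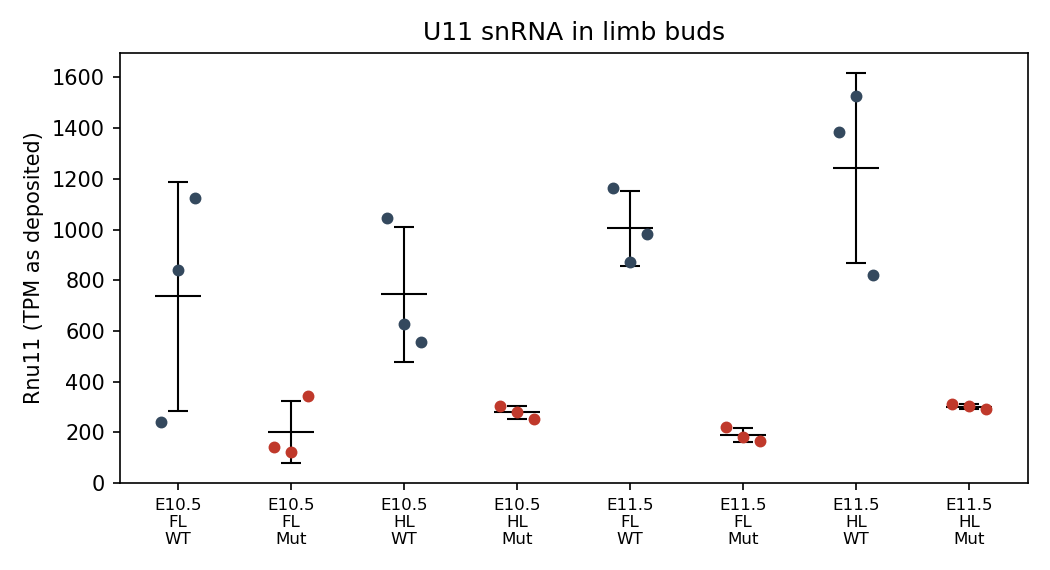
Rnu11 in TPM as deposited for each of the 24 libraries, grouped by stage, limb and genotype; points are libraries, bars are group means and error bars SD over 3 libraries. Mutant means are 202.1, 279.2, 189.4 and 301.4 TPM against WT means of 736.2, 743.9, 1005 and 1244 TPM.

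Structural RNA made up 61.8% to 81.3% of TPM at E10.5 and 73.3% to 83.9% at E11.5, led in most libraries by the 7SL genes Rn7s1 and Rn7s2. Nuclear protein-coding genes held 14.9% to 32.8% and 13.6% to 22.9%. In E11.5 FL they held 21.3 ± 2.79% in mutants and 15.6 ± 1.42% in WT, and the median log2 change of all genes on the deposited scale was 0.39. That median was -0.14 in E10.5 FL, 0.11 in E10.5 HL and -0.10 in E11.5 HL. After rescaling the medians were -0.01, 0.00, -0.01 and -0.04. In E11.5 FL, 3733 genes passed the limma threshold on the deposited scale (3691 higher, 42 lower; 98.9% higher), and 183 did after rescaling (52 higher, 131 lower; 28.4% higher). Only 76 of these passed on both scales in one direction. Among nuclear protein-coding genes alone, summed anew to a common total, 103 passed (48 higher, 55 lower). The count rests on single libraries too: after rescaling it was 358 without WT replicate 1 and 317 without mutant replicate 1, but 35, 40, 28 and 68 without WT replicate 2, WT replicate 3, mutant replicate 2 and mutant replicate 3. On the deposited scale these last 4 gave 21, 23, 8 and 36, and the first pair 5435 and 5349.

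**Figure D2:**
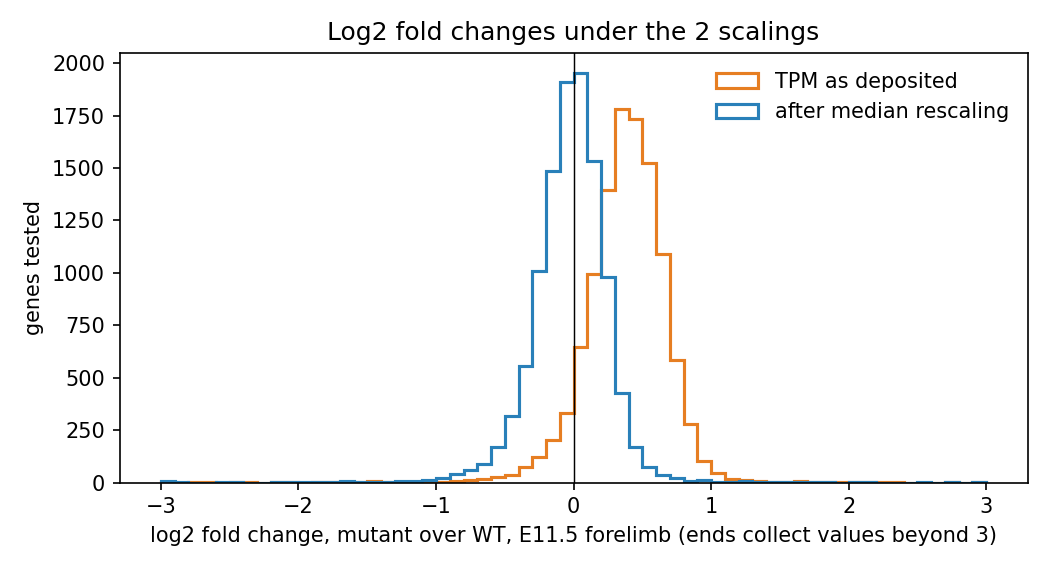
Histograms of log2 fold changes, mutant against WT, of all genes tested in E11.5 FL, on the deposited scale and after rescaling; the y axis counts genes and the end bins collect values beyond 3. The median is 0.39 on the deposited scale and -0.01 after rescaling.

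Several libraries stood apart within their groups. Xist was at least 5 TPM in 6 libraries, all mutant: E10.5 FL replicates 1 (25.6 TPM) and 3 (5.72 TPM), E10.5 HL replicates 1 (45.3 TPM) and 3 (13.7 TPM), E11.5 FL replicate 3 (31.5 TPM) and E11.5 HL replicate 3 (21.5 TPM). In E10.5 FL mutant replicate 3 the Y-linked gene Ddx3y was also present at 4.62 TPM. That library held hindlimb markers as well: Hoxc10 at 4.44, Pitx1 at 1.73 and Tbx4 at 1.91 rescaled TPM, against at most 0.404 for Hoxc10 and 0.109 for Pitx1 in any other E10.5 FL library. Tbx5, the forelimb marker, was 2.05 in it and 2.65 in E10.5 FL WT replicate 1, against 6.12 to 11.9 in the other E10.5 FL libraries.

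The E10.5 FL comparison asked which genes differed at the earlier stage. Capns1, a calpain subunit gene, fell by 0.75 ± 0.09 (adjusted p = 0.03; 16.7 ± 0.437 against 28.8 ± 1.33, no overlap between the 3 and 3 libraries). It lies on chromosome 7 at 30186936 to 30198811. The other calls, named after their values were seen, were Gm28037 (-6.42, adjusted p = 0.03; listed at 0 in every mutant library) and Gm17530 (3.72, adjusted p = 0.0331). Each of these 3 calls was lost whenever any of the 6 libraries was left out (adjusted p up to 0.276 for Capns1 and Gm17530 and 0.259 for Gm28037). The 3 calls were 1 rise and 2 falls, with 634 genes at an unadjusted p under 0.05; the deposited scale gave 3 calls as well, with 2 genes shared. Restricted to protein-coding genes, limma called 0, with 596 at an unadjusted p under 0.05.

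Gene lists in E10.5 FL moved mostly without single-gene calls: camera passed 7 of 26 lists with its preset correlation, and 0 with an estimated correlation (adjusted p = 0.601 for each). Erythroid genes were higher (median 0.60, 13 of 15 members higher, adjusted p = 1.67e-07), with embryonic globins Hbb-bh1 at 1478 ± 182 against 711.5 ± 101 and Hbb-y at 2266 against 1273. Limb mesenchyme genes were lower (median -0.34, 24 of 24 lower, adjusted p = 7.62e-06), among them Col1a2 (-0.62), Cdh11 (-0.58) and Tbx18 (-0.86). Leaving out the Xist-positive libraries, chosen after seeing the data, leaves 1 mutant library here (replicate 2), which the fit assumes to vary like the other groups, so it cannot tell sex from the loss of libraries. That list then stood at adjusted p = 0.253 (1.37e-07 to 0.601 over its alternatives), but it passed with each single library left out. SHH pathway genes (-0.28, 16 of 17 lower, adjusted p = 0.000957), with Hand2 at -0.99, Osr1 at -0.72 and Grem1 at -0.72, and proximodistal genes (-0.31, 16 of 21 lower, 0.00656), with Shox2 at -1.09 and Cyp26b1 at -0.90, were lower. Without WT replicate 3 these lists stood at adjusted p = 0.129 and 0.0769. Surface ectoderm genes were higher (0.21, 18 of 20, 0.000957; Krt8 0.62, Cldn6 0.46), but not without mutant replicate 3 (0.218). Minor-intron genes were slightly lower (-0.11, 52 of 75, 0.00482), but not without WT replicate 1 (0.0702). Cytosolic ribosomal protein genes were higher (0.21, 73 of 78, 9.81e-09), Rpl41 by 0.41 (0.477 on that 1 mutant library; 1.46e-23 to 0.601 over the alternatives). Adjusted over the list alone, 1 erythroid gene passed, against 0 over all genes. The p53 targets were at 0.08 (19 of 30 higher, adjusted p = 0.188, -0.02 on the deposited scale).

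The E10.5 HL comparison put the same question to the later-developing limb. AC154540.1, a symbol with no match in the GENCODE M21 annotation, was the only call (-6.41 ± 0.74, adjusted p = 0.027). It was listed at 0 in the 3 mutant libraries and at 116 ± 116 in WT; the call was lost without WT replicate 1 or without any of the mutant replicates (adjusted p up to 0.235). At an unadjusted p under 0.05 there were 228 genes, and without WT replicate 2 limma called 3. On protein-coding genes alone limma called 0, with 240 at an unadjusted p under 0.05. Camera passed 4 of 26 lists, and 0 with an estimated correlation. Sex-linked genes were lower (median -2.30, adjusted p = 0.011, 0.423 with an estimated correlation) with Xist-positive libraries among the mutants only; adjusted over the list alone, 1 rose and 4 fell, against 0 over all genes. G2/M genes (-0.07, but 0.04 on the deposited scale; 37 of 49 lower, 0.0217, 0.938 with an estimated correlation) included Top2a at -0.22. Myogenic genes (-0.40, 6 of 7 lower, 0.0367, 0.423 with an estimated correlation) included Pax3 at -0.63 and Met at -0.47. Surface ectoderm genes (-0.09, 17 of 20 lower, 0.0367, 0.939 with an estimated correlation) included Dsp at -0.67. Without WT replicate 1 or mutant replicate 1 the G2/M (0.108, 0.0682), myogenic (0.104, 0.0682) and surface ectoderm (0.0945, 0.92) calls were lost, and the sex-linked call was lost without mutant replicate 1 (0.0682) or WT replicate 3 (0.0786). G2/M was also lost without WT replicate 2 (0.0961), and the myogenic and surface ectoderm calls without WT replicate 3 (0.122, 0.157) or mutant replicate 2 (0.213, 0.315). The p53 targets (-0.05), limb mesenchyme (-0.07), SHH pathway (0.02), proximodistal (0.02), erythroid (-0.03) and minor-intron (-0.003) lists did not pass; p53 targets, limb mesenchyme, erythroid and minor-intron genes had medians above 0 on the deposited scale (0.04, 0.04, 0.07 and 0.11).

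The E11.5 FL comparison asked what had changed a day later. The largest rises under the naming rule were in p53 target genes. Eda2r, a receptor of the tumor necrosis factor family, rose (2.04 ± 0.17, adjusted p = 0.000495; 5.09 ± 1.70 against 0.442 ± 0.049; chromosome X, 97333840 to 97377216). Ccng1, encoding cyclin G, rose 3.48-fold (1.64 ± 0.20, 0.00244; 27.8 ± 8.68 against 7.99 ± 1.01; chromosome 11, 40748552 to 40755311), and the exonuclease gene Aen 2.14-fold (0.93 ± 0.12, 0.00506; 8.21 against 3.83). Of 30 p53 targets 9 rose and 0 fell over all genes, and adjusted over the list alone 14 rose and 1 fell; 25 were higher in mutants. The other risers in the list, Cdkn1a (1.12, adjusted p = 0.0174), Sesn2 (0.92, 0.0302), Phlda3 (0.91, 0.0391), Bax (0.67, 0.0191), Dcxr (0.64, 0.0244) and Psrc1 (0.51, 0.0474), were each lost when some single library was left out: all 6 without WT replicate 2, WT replicate 3 or mutant replicate 2. Sesn2, Phlda3 and Psrc1 were also lost without mutant replicate 1, and Phlda3 and Psrc1 without WT replicate 1 (adjusted p up to 0.0855 for Cdkn1a and 0.179 for the others). Without a mutant library Cdkn1a and Eda2r fell under the filter on low values, so those fits, chosen after seeing the data, kept the genes of the fit to all libraries. Camera gave the list adjusted p = 4.49e-09 (median 0.29), but adjusted p = 0.723 with an estimated correlation (unadjusted 0.0442). Zmat3 (0.66, 0.0714), Mdm2 (0.22, 0.269), Perp (-0.35, 0.331, 0.09 on the deposited scale) and Sesn1 (-0.34, 0.066, 0.04 on the deposited scale) did not pass.

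**Figure D3:**
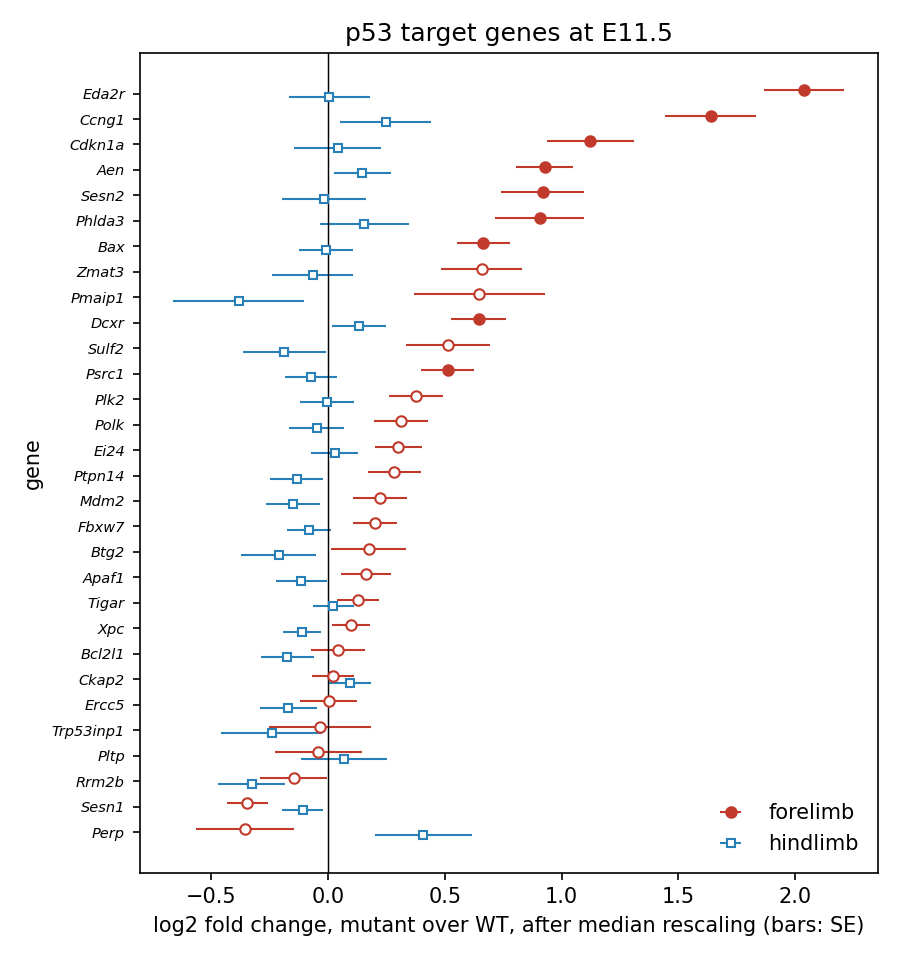
Log2 fold change, mutant against WT, with its standard error after rescaling for 30 p53 target genes at E11.5; circles are FL, squares HL (3 against 3 libraries each), and filled symbols have an adjusted p under 0.05. In FL 9 are filled, led by Eda2r at 2.04; in HL none is, and Eda2r is at 0.01.

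Among the falls in E11.5 FL, Rpl28, a ribosomal protein gene, was lowest after Rnu11 (-2.58 ± 0.08, adjusted p = 2.46e-08; 12.7 ± 0.963 against 80.8 ± 3.15; chromosome 7, 4792874 to 4795066). Lage3 (-1.13 ± 0.12, 0.00108), the kinetochore gene Spc24 (-0.96 ± 0.11, 0.00137), Sptssa (-0.96 ± 0.09, 0.000702) and the snoRNA gene Snora78 (-1.56 ± 0.31, 0.0313) followed; Snora78 was lost without each library but WT replicate 1 (up to 0.12). Of 71 minor-intron genes listed by hand, 6 fell and 0 rose over all genes, and adjusted over the list alone 17 fell and 4 rose. Among the fallers were Spc24, Kifap3 (-0.81 ± 0.08, 0.000959; 3.42 ± 0.160 against 6.74 ± 0.172), Ift80 (-0.64, 0.0291), Thoc2 (-0.62, 0.0439) and Polr2e (-0.49, 0.0284, 0.01 on the deposited scale). Ift80 and Polr2e were lost without WT replicate 2, WT replicate 3 or mutant replicate 2, and Thoc2 without each library but mutant replicate 1 (up to 0.103, 0.123 and 0.164). The list's median was -0.13 (0.31 on the deposited scale; 44 lower; camera adjusted p = 0.0153, 0.723 with an estimated correlation, 0.0769 on the deposited scale and 0.0849 without WT replicate 1). Spc24, Kifap3, Lage3, Sptssa, Rpl28, Sox6, Aen, Ccng1, Rnu11 and Eda2r passed in all 6 leave-outs, but on the deposited scale Spc24 (-0.50, 0.0559), Kifap3 (-0.39, 0.0981) and Sox6 (-0.50, 0.0561) did not, nor Sox6 with all 24 libraries (0.0739). Other named rises were Snhg3 (0.90, 0.0447), Cpne1 (0.79, 0.0291) and Gtse1 (0.74, 0.0291). Snhg3 was lost without any of the 6 libraries; Cpne1 without WT replicate 2 or 3 or mutant replicate 2 or 3; Gtse1 without WT replicate 2 or 3 or mutant replicate 2 (adjusted p up to 0.13, 0.129 and 0.128).

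Few patterning and growth genes in E11.5 FL passed. Etv4, a target of FGF signalling from the apical ridge, rose (0.52, adjusted p = 0.0313) and the receptor gene Fgfr2 fell (-0.35 ± 0.08, 0.0462), though Fgfr2 was at 0.14 on the deposited scale (0.526); the list's median was 0.08 (0.3). Etv4 was lost without WT replicate 2 or 3 or mutant replicate 2 or 3 (up to 0.138), and Fgfr2 without any of the 6 libraries (up to 0.155). Tbx5, the forelimb identity gene, was at 0.02 (0.922). The limb identity (0.01, adjusted p = 0.488), SHH pathway (0.11, 0.284), proximodistal (0.06, 0.188), limb mesenchyme (0.02, 0.845), G1/S (0.07, 0.237) and G2/M (-0.07, 0.275, 0.42 on the deposited scale) lists did not pass, and 4 dorsoventral genes had a median of 0.20, too few for camera. Chondrogenic genes were lower (-0.40, 13 of 14, 0.00321, 0.723 with an estimated correlation): Sox6 fell (-0.90 ± 0.12, 0.00639; 2.85 ± 0.228 against 6.25 ± 1.20), with Sox9 at -0.56 (0.206) and Col2a1 at -0.45 (0.289, 0.03 on the deposited scale). Replication-dependent histone genes were lower (-0.43, but 0.07 on the deposited scale; 61 of 66, 4.74e-10, 0.723 with an estimated correlation), Hist1h1c at -0.84 and Hist1h1e at -0.65; adjusted over the list alone 1 rose and 11 fell, against 0 over all genes. Genes of the integrated stress response were higher (0.17, 13 of 17, 0.00377, 0.723 with an estimated correlation), of which Sesn2 rose; adjusted over the list alone 5 rose.

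Markers of other cell types in E11.5 FL went in different directions. Endothelial genes were higher (median 0.23, 13 of 15, camera adjusted p = 0.0153, 0.766 with an estimated correlation, 0.174 on the deposited scale), Plvap at 0.67 (0.12); the list was lost without WT replicate 1 (0.0924) or mutant replicate 2 (0.0711). Myeloid (0.32, 0.171), erythroid (0.16, 0.3), surface ectoderm (-0.12, 0.249), neural (-0.12, 0.256) and myogenic (-0.18, 0.988, camera's direction being up) lists did not pass. In the neural list Gap43 rose (0.60, 0.0488) and Cadm2 fell (-0.82 ± 0.13, 0.0114; lost without WT replicate 2, 0.0599). Gap43 was lost without any library but mutant replicate 1 (up to 0.161). Krt14 was at -0.95 (0.244). Further lists without a call were apoptosis effectors (0.01, 0.988), glycolysis and hypoxia (0.05, 0.496), interferon-stimulated genes (-0.08, 0.464), mitochondrially encoded genes (-0.20, 0.188), cytosolic ribosomal proteins (-0.07, 0.233; Rpl28 fell), minor spliceosome proteins (0.03, 0.379), where Ccdc84 rose (0.77, 0.0153; lost without WT replicate 2 or mutant replicate 2, up to 0.0902), and spliceosomal snRNA (-0.17, 0.188), where Rnu11 fell. The 4 sex-linked genes had a median of -1.42, with 1 Xist-positive library among the mutants. The snRNA list did pass on the deposited scale (adjusted p = 1.96e-09, and 0.0216 with an estimated correlation). On that scale the medians of the surface ectoderm (0.28), neural (0.18), myogenic (0.14), interferon (0.24), mitochondrial (0.31), ribosomal protein (0.44) and snRNA (0.27) lists were above 0.

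The E11.5 HL comparison asked the same of the hindlimb. Rpl28 fell (-2.999 ± 0.084, adjusted p = 4.5e-09; 9.83 ± 0.576 against 85.6 ± 6.09). The only other call, named after its values were seen, was Gm24405 (-2.11, 0.00474), listed at 0 in the mutants. With all 24 libraries neither passed (0.178 for Rpl28, 0.502 for Gm24405), and Gm24405 was also lost with a pseudocount of 0.1 (0.088) and with only the 6 libraries (0.121). At an unadjusted p under 0.05 there were 692 genes, and without mutant replicate 1 or mutant replicate 3 there were 5 and 4 calls, against 2. Without WT replicate 2 there was 1. None of the 30 p53 targets passed in limma (median -0.06, 11 higher, camera adjusted p = 0.946): Eda2r was at 0.01, Ccng1 at 0.25 and Cdkn1a at 0.04. Camera passed 5 of 25 lists, and 0 with an estimated correlation (adjusted p = 0.863 at the lowest). Surface ectoderm genes were higher (0.24, 20 of 22, 2.63e-09, 0.863 with an estimated correlation), with the keratins Krt8 at 0.96, Krt18 at 0.65 and Krt19 at 0.62. Chondrogenic genes were lower (-0.40, 13 of 14, 0.0012, 0.863 with an estimated correlation), with Col9a1 at -0.55, Col2a1 at -0.50 and Sox6 at -0.48; adjusted over the list alone 1 fell. SHH pathway genes were lower (-0.36, 14 of 18, 0.0293, 0.893 with an estimated correlation), with Ptch1 at -0.43, Gli1 at -0.42 and the distal Hox gene Hoxd13 at -0.83. Cytosolic ribosomal protein genes were higher (0.17, 76 of 78, 2.1e-16, 0.863 with an estimated correlation), as were G1/S genes (0.04, but -0.03 on the deposited scale; 24 of 39, 0.00293, 0.863 with an estimated correlation). Without mutant replicate 3 the chondrogenic (0.0632), SHH (0.165) and G1/S (0.0723) calls were lost, and SHH also without WT replicate 2 (0.185). Minor-intron genes were at -0.05 (0.556). Prrx1 (-0.39), Tbx4 (-0.31) and Pitx1 (-0.27) did not pass.

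Whether the mutant effect differed between limbs was tested by an interaction term within each stage. At E11.5 the effect on Eda2r was lower in HL than in FL by -2.03 ± 0.24 (adjusted p = 0.0369), the only call after rescaling. It was lost without each library but FL mutant replicate 1 or 3 (up to 0.177), with no filter (0.168) and with the replicate as a block (0.28). Ccng1 (-1.39, 0.209), Cdkn1a (-1.08, 0.299), Aen (-0.78, 0.274) and Rnu11 (0.997, 0.341) did not pass. As a list, p53 targets passed (median -0.38, camera adjusted p = 2.85e-08, 0.671 with an estimated correlation), and adjusted over the list alone 11 were lower. Camera passed 6 lists: besides p53 targets, histones (0.42, 2.38e-10), ribosomal proteins (0.25, 2.85e-08), surface ectoderm (0.42, 22 of 22, 6.78e-06), SHH pathway (-0.49, 0.0272) and stress response (-0.24, 0.00268), 0 with an estimated correlation; histones (-0.15), ribosomal proteins (-0.33) and surface ectoderm (-0.04) were below 0 on the deposited scale. At E10.5 limma called 0 genes after rescaling, with 293 at an unadjusted p under 0.05, and Rnu11 was at 0.12 (1). Camera passed 9 lists, 0 with an estimated correlation (adjusted p = 0.468 at the lowest), among them erythroid (-0.61, 5.56e-06), surface ectoderm (-0.39, 5.56e-06), limb mesenchyme (0.33, 0.000854) and minor-intron genes (0.11, 0.0118). Before rescaling the median of all genes was 0.24 at E10.5 and -0.50 at E11.5.

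Whether the effect differed between stages was tested over all 24 libraries, where the shorter E10.5 reads go with stage in both genotypes. In FL 7 genes passed, 4 higher at E11.5 and 3 lower. Eda2r (1.70 ± 0.23, adjusted p = 0.00228), the ubiquitin ligase gene Wsb2 (1.11 ± 0.17, 0.00758) and the vesicle transport gene Rab8a (0.95 ± 0.17, 0.038) were higher. Snora78 (-3.50 ± 0.62, 0.038) and Ap4s1 (-0.87 ± 0.16, 0.042) were lower. The remaining Gm28037 (6.36, 0.00146) and Gm17530 (-6.60, 0.00622) were named after their values were seen. At E11.5 Gm28037 was at most 0.18 TPM in the FL libraries, so its value is the E10.5 difference with the sign turned. Eda2r, Wsb2, Gm28037 and Gm17530 passed in 12 of 12 leave-outs (Wsb2 not on the deposited scale, 0.056), Rab8a only without E11.5 WT replicate 1 or E11.5 mutant replicate 3 (else up to 0.167), Snora78 only without E10.5 WT replicate 1 or mutant replicate 2 of either stage (up to 0.141), and Ap4s1 only without E10.5 WT replicate 3 (up to 0.164). Camera passed 12 lists, 0 with an estimated correlation (adjusted p = 0.338 at the lowest), led by histones (-0.58, 2.92e-06), p53 targets (0.25, 3.28e-06) and ribosomal proteins (-0.27, 3.28e-06); histones (0.11) and ribosomal proteins (0.41) were above 0 on the deposited scale. SHH pathway (0.41, 0.00119), proximodistal (0.40, 0.00104) and limb mesenchyme genes (0.38, 0.003) were also higher at E11.5. In HL AC154540.1 was the only call (6.20, 0.00279; 12 of 12 leave-outs), with 309 genes at an unadjusted p under 0.05. It is listed at 0 in every E11.5 library, WT and mutant, so this is the E10.5 difference with the sign turned, and that call was lost in 4 of 6 leave-outs. Camera passed surface ectoderm (0.47, 3.76e-09, 0.717 with an estimated correlation), ribosomal protein (0.11, 0.000105) and G2/M genes (0.10, 0.00203) there, 0 with an estimated correlation; the last pair were at -0.07 and -0.08 on the deposited scale. Rnu11 was at -1.33 (0.441) in FL and -0.46 (1) in HL.

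The comparisons of HL with FL asked whether limb identity genes still parted the limbs in mutants. In E11.5 WT Pitx1 (4.11 ± 0.15, adjusted p = 5.66e-08; 18.6 against 0.127), Tbx4 (2.39 ± 0.15, 7.32e-06), Hoxc10 (2.09 ± 0.08, 6.93e-08), Hoxc11 (1.38, 4.62e-05) and Isl1 (1.35, 8.55e-05) were higher in HL, and Tbx5 was lower (-2.95 ± 0.11, 5.66e-08; 0.0230 against 6.89). In E11.5 mutants the values were Pitx1 3.87 and Tbx5 -2.79 (7.39e-08 each), Tbx4 1.94 (7.32e-05), Hoxc10 2.08 (7.39e-08), Hoxc11 1.13 (0.000302) and Isl1 1.28 (0.000189). These calls passed in all 6 leave-outs of each comparison, but with all 24 libraries Isl1 was lost in WT (0.899) and in mutants (0.466), and Hoxc11 in mutants (0.11). Hoxc5 (-0.24) and Hoxc6 (-0.18) did not pass in WT. In WT 16 genes passed (9 higher, 7 lower), and in mutants 43 (24 higher, 19 lower; 55.8% higher), against 5140 on the deposited scale (0.545% higher, median of all genes -0.44), of which 31 were shared. That deposited count was 26, 257, 218 and 62 without FL mutant replicates 2 and 3 and HL mutant replicates 1 and 2. Mutant HL was below mutant FL in Eda2r (-1.94, 0.000203), Ccng1 (-1.59, 0.00379) and Cdkn1a (-0.999, 0.0499). Igf1 was higher in HL in WT (1.71, 0.000305) and in mutants (1.09, 0.0134; lost without FL mutant replicate 1 or 2, up to 0.0826).

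At E10.5 fewer of these genes passed, with larger standard errors. In WT Pitx1 (3.56 ± 0.40, adjusted p = 0.0111; 12.4 ± 6.91 against 0.0526), Hoxc10 (3.00 ± 0.48, 0.0461) and Tbx4 (2.48 ± 0.32, 0.0236) were higher and Tbx5 lower (-2.80 ± 0.43, 0.0412), among 17 calls (7 higher, 10 lower; 41.2% higher against 53.3% on the deposited scale, where the median of all genes was 0.22). Gria2 was lower (-2.37 ± 0.24, 0.00716). Hoxc10 and Tbx4 were lost without any of the 6 libraries (up to 0.208 and 0.106), Pitx1 without FL WT replicate 2 or HL WT replicate 2 (up to 0.0856), Gria2 without HL WT replicate 2 (0.0613) and Tbx5 without any library but FL WT replicate 1 (up to 0.198). Isl1 (2.31, 0.293), Hoxc11 (1.40, 0.276) and Hoxc9 (0.70, 0.291) did not pass. In mutants Pitx1 (3.23 ± 0.40, 0.0166) and Tbx4 (2.57 ± 0.32, 0.0166) were higher, among 7 calls (3 higher, 4 lower; 42.9% higher against 66.7% on the deposited scale, where the median of all genes was 0.45), both lost without any library but FL mutant replicate 3 (up to 0.123). Hoxc10 (2.22, 0.239), Tbx5 (-2.19, 0.196; 0.193 against 4.78) and Isl1 (1.80, 0.717) did not pass. Hoxc10 did pass on the deposited scale (2.66, 0.0243), and Hoxc10 (2.11) and Tbx5 (-2.05) with all 24 libraries (0.00923 each). Without FL mutant replicate 3, which carried hindlimb markers, Hoxc10 (3.03, 0.000299) and Isl1 (2.92, 0.0181) passed and Tbx5 did not (-2.64, 0.0612). Over the alternatives adjusted p reached 0.872, 0.76 and 1 for Hoxc10, Tbx5 and Isl1. AC154540.1 was listed at 0 in mutant HL and at a mean of 248 in mutant FL (-7.88, 0.00327). Here FL and HL libraries of equal replicate number resembled each other, and with the replicate as a block 24 genes passed on the deposited scale, against 6 (13 without FL mutant replicate 3 and 3297 without HL mutant replicate 3).

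**Figure D4:**
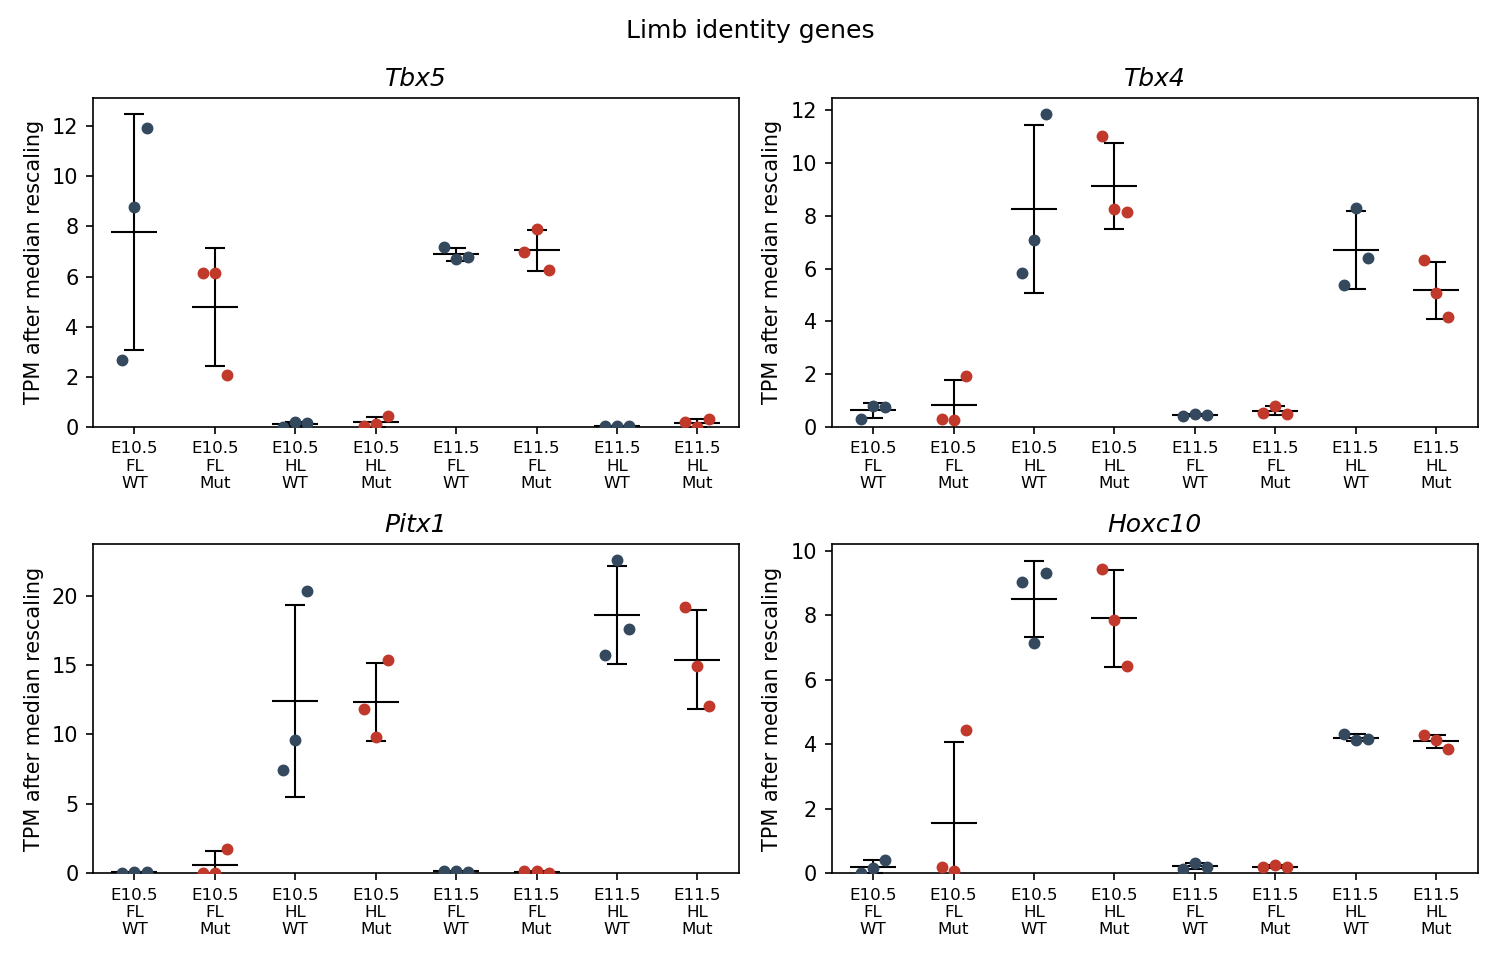
Tbx5, Tbx4, Pitx1 and Hoxc10 in rescaled TPM for each of the 24 libraries, by stage, limb and genotype; points are libraries, bars means and error bars SD over 3 libraries. At E11.5 Tbx5 is lower and Pitx1 higher in HL than in FL in WT (log2 -2.95 and 4.11) and in mutants (-2.79 and 3.87).

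Stage was compared in WT libraries for reference, where any effect of the shorter E10.5 reads cannot be separated from development. In FL 4765 genes passed after rescaling (2517 higher at E11.5, 2248 lower; 52.8% higher) and 2723 before (8.19% higher; median of all genes -0.27), with 2310 shared. In HL 5006 passed (2738 higher, 2268 lower; 54.7% higher) against 4281 before (6.31% higher; median -0.42), with 2537 shared. The deposited counts fell to 1360, 1206 and 1468 in FL without E10.5 WT replicate 2, E11.5 WT replicate 2 and E11.5 WT replicate 3, and to 2830 and 2577 in HL without E10.5 and E11.5 WT replicate 1. Rny3 and Snord13 are listed at 0 in all 12 E11.5 libraries, so in FL their calls (adjusted p = 0.00588 and 2.56e-10) cannot be told apart from a difference in what was prepared or counted at that stage, and no lower expression is read from them. The U1 gene Rnu1b2 was lower in FL (-9.01, 7.95e-06) and HL (-8.04, 1.93e-05) while its other copy Rnu1b1 was higher (3.02, 0.00488, and 4.20, 0.000372), so no change of U1 as a whole is read from either. In FL Scarna8 (4.77, 0.0129) and Hist1h2bq (3.43, 4.43e-05) were higher. In HL Hist1h2bq (4.31, 3.84e-06) and Snora5c (4.19) were higher. AY036118 (-14.06, 0.000291), Lars2 (-10.81, 3.62e-05) and Rn18s-rs5 (-10.20, 0.00026) were listed far lower at E11.5 in HL. Their means there were 0.326, 2.15 and 10.6 against 22160, 5507 and 13260. Such falls cannot be told apart from a difference in what was prepared or counted at that stage, and no lower expression is read from them. Rnu11 was at 1.15 (0.0697) in FL, and higher at E11.5 in HL (1.38, 0.0303), a call lost without E10.5 HL WT replicate 2 or 3 or E11.5 HL WT replicate 1 or 2 (up to 0.113).

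Genes lower in mutants of both limbs at E11.5 included several on chromosome 7, a tally made after the values were seen. Of 16 genes with an unadjusted limma p under 0.01 in FL and in HL, 15 lower and 1 higher, 8 lie on chromosome 7: Rpl28, Capns1, Sox6, Tbcb, Trim12c, Alkbh6, Zfp420 and, as the only one higher, Slc1a5. Capns1 was at -0.75, -0.61, -1.02 and -1.14 in E10.5 FL, E10.5 HL, E11.5 FL and E11.5 HL, and its neighbour Tbcb at -0.43, -0.51, -0.74 and -0.97. Capns1 passed the adjusted threshold only in E10.5 FL (adjusted p = 0.063 in E11.5 FL and 0.734 in E11.5 HL). In E11.5 the Xist-positive mutant replicate 3 stood nearest to WT: Capns1 was 16.5 rescaled TPM in it in each limb, against 9.05 and 11 in the other FL mutants (WT at least 22.2) and 8.67 and 7.51 in the other HL mutants (WT at least 21.9), and Tbcb 12.3, 14.9 and 23.3 (WT at least 26.3) and 14.5, 11.9 and 19.7 (WT at least 28.9). As deposited, Tbcb in that FL library (33.1 TPM) lay above every FL WT library. Rpl28 was at -0.34 ± 0.75 in E10.5 FL (0.978) and -0.23 ± 0.75 in E10.5 HL (1). In rescaled TPM it was 69.3, 70.1 and 217.2 in mutants against 89.9, 71.0 and 340 in WT for E10.5 FL, and 77.0, 91.2 and 200.3 against 65.0, 90.0 and 386 for E10.5 HL, replicate 3 being the highest of each group. The difference of its mutant effect between stages was -2.26 ± 0.81 in FL (0.281) and -2.80 ± 0.81 in HL (1). That fit has no term for the replicate number.

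**Figure D5:**
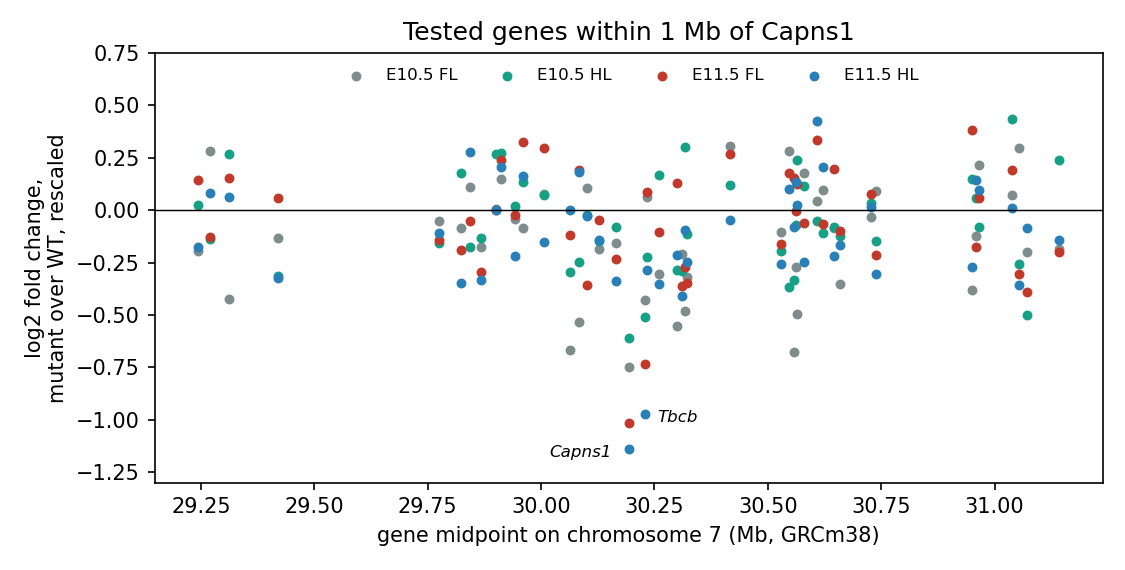
Log2 fold change, mutant against WT after rescaling, of the genes tested within 1 Mb of Capns1 on chromosome 7 in the 4 mutant comparisons (3 against 3 libraries each); the x axis is position in Mb (GRCm38). Capns1 is at -0.75, -0.61, -1.02 and -1.14 and Tbcb at -0.43, -0.51, -0.74 and -0.97.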

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

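In this part the test of other cell types and the splits after rescaling of differences between effects were chosen only after the result was seen. The results here are differences between the mutant effects of the limbs or of the stages that passed an interaction test.

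At E11.5 the mutant effect on p53 targets differed between limbs: the list stood at -0.38 in HL relative to FL (camera adjusted p = 2.85e-08, 0.671 with an estimated correlation). Eda2r stood at -2.03 (0.0369) after rescaling and -2.40 (0.000275) as deposited, though after rescaling it passed in only 2 of 12 leave-outs (without FL mutant replicate 1 or 3; else up to 0.177), and neither with no filter (0.168) nor with the replicate block (0.28). Of 100 drawn splits, the real one included, 63 gave at least as many genes as this 1 after rescaling. Those splits reassign genotype within each limb, so some carry the genotype effect of both limbs. They therefore cannot decide whether a difference between limbs arose by chance. Ccng1 stood at -1.94 (0.00919) as deposited but -1.39 (0.209) after rescaling. A smaller share of structural RNA in mutant FL moves the TPM of all other genes by a common factor. Rescaling takes that factor out before 1 is added, so alone it could not set the list apart after rescaling. Summing protein-coding genes anew takes out such a shift whatever its cause, so its outcome was fixed in advance and adds no support. The list then stood 0.437 above all genes with 9 of 37 risen (camera adjusted p = 3.31e-11). Without the female-like mutant library the list still stood 0.356 above all genes (camera adjusted p = 5.32e-11, 8 of 28 risen). The rise is thus not carried by that library alone, though camera passed in other splits of these libraries too. Lists of other cell types did not rise together after rescaling, which goes against a larger share of all of them as the whole cause. The upper quartile of neural genes was -0.0882, while the quartiles were 0.105 to 0.312 for endothelial and 0.0789 to 0.507 for myeloid genes. The myeloid list did not pass, nor the endothelial list with an estimated correlation (camera adjusted p = 0.766), so a change in those types stays open. Among the 10 splits of the 6 FL libraries 1 (the real one) called as many p53 targets (9, highest other 0). That is too few splits for a share under 0.05. Camera passed in 4 of the 10, and the absolute list median was 0.292 in the real split and up to 0.271 in the others. A p53 response to loss of U11 in FL stays a hypothesis, found and tested on the same libraries. Camera gave the FL list an adjusted p of 0.723 when the correlation was estimated.

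Other differences between limbs passed on the deposited scale alone. They were AC154540.1 (-6.77, 0.00745) and Gm28037 (7.65, 0.00745) at E10.5, and Gm24405 (-2.05, 0.00919) at E11.5, which is listed at 0 in mutant HL. Of 100 drawn splits, the real one included, 14 gave as many genes at E10.5 (2) and 26 at E11.5 (3). As such splits can carry the genotype effect of both limbs, chance is neither shown nor excluded. The highest others, 6739 and 7669, point to a structure of the samples in scale: in those splits the median of all genes was 0.845 and -0.669, and after rescaling they called 0 and 5 genes. At E11.5 another split called 70 after rescaling against the real 1 (at E10.5 the highest was 2). Scale thus does not account for all of it there, and the part of the genotype effect was not tested.

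Differences of the FL effect between stages were Eda2r at 2.02 (0.00128), Gm28037 at 6.46 (0.00133) and Gm17530 at -6.12 (0.00837) as deposited. After rescaling they were Eda2r at 1.70 (0.00228), Wsb2 at 1.11 (0.00758), Rab8a at 0.95 (0.038), Gm28037 at 6.36 (0.00146), Gm17530 at -6.60 (0.00622), Snora78 at -3.50 (0.038) and Ap4s1 at -0.87 (0.042). In HL AC154540.1 stood at 6.56 (0.000131) as deposited and 6.20 (0.00279) after rescaling. AC154540.1 is listed at 0 in every E11.5 library and Gm28037 is at most 0.18 TPM in E11.5 FL, so for both there is no E11.5 effect to compare, and the value is the E10.5 difference with its sign turned. Of 100 drawn splits, the real one included, 13 in FL and 37 in HL gave as many as these deposited counts (3 and 1). After rescaling (7 and 1) 6 and 30 did. These splits reassign genotype within each stage and can carry the genotype effect of both stages, so chance is neither shown nor excluded. The highest others, 5090 and 4835, point to a structure of the samples in scale: there the median of all genes was 0.742 and -0.692. After rescaling the second called 0 genes (highest other split 2), but the first still called 45 (highest other 48) against the real 7. Scale thus does not account for all of it, and the part of the genotype effect was not tested.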

How the results depend on the processing

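The alternatives chosen after seeing the data were protein-coding genes only, leaving out Xist-positive libraries, rescaling joined to other settings, and keeping the genes of the full fit where a named gene fell under the filter without a library. Leaving out the Xist-positive libraries leaves 1 mutant library in each E10.5 limb, assumed to vary like the other groups, so those counts say little. Among named genes after rescaling, 505 results under other settings and 601 with 1 library left out kept their side of the threshold. A further 156 and 223 no longer passed, and 12 and 4 newly passed. Direction was compared only where a gene passed before or after the change, so genes that passed in neither may have changed sign. Among those compared 2 reversed: Fgfr2 (0.136) and Polr2e (0.00618) in E11.5 FL on the deposited scale. Reversal there goes with the shift of all genes, while the cause of the other changes was not tested. Depth cannot be recovered from TPM, so what it limits was not tested either.

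Genes past the threshold on the deposited scale were as follows, ranges being those with each library left out. For E10.5 FL (3): 0 with no filter, 58 with only the 6 libraries, 0 for protein-coding genes, 5 without Xist-positive libraries, range 1 to 8. For E10.5 HL (1): 0 with no filter, 83 with only the 6 libraries, 2 with all 24, 0 for protein-coding genes, 3 without Xist-positive libraries, range 1 to 4. For E11.5 FL (3733): 67 with no filter, 183 rescaled, 11 with all 24 libraries, 2139 with the replicate block, 103 for protein-coding genes, 36 without the Xist-positive library, range 8 (without mutant replicate 2) to 5435 (without WT replicate 1). For E11.5 HL (4): 2 rescaled, 102 with only the 6 libraries, 1 with all 24, 1 for protein-coding genes, range 3 to 8. At an unadjusted p under 0.05 limma had 596 and 240 protein-coding genes where it called 0 in E10.5 FL and HL.

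With rescaling kept, E10.5 FL (3) gave 1 with only the 6 libraries, 1 with the replicate block, 1 without Xist-positive libraries, range 0 to 2. E10.5 HL (1) gave 4 with only the 6 libraries, 0 with the block, range 0 to 3. E11.5 FL (183) gave 39 with only the 6 libraries, 78 with the block, 68 without the Xist-positive library, range 28 (without mutant replicate 2) to 358 (without WT replicate 1). E11.5 HL (2) gave 4 without the Xist-positive library, range 1 to 5.

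Lists past the threshold on the deposited scale were 0 with an estimated correlation in E10.5 FL (9; range 6 to 12). In E10.5 HL (5) they were 2 with an estimated correlation, 1 with only the 6 libraries, 2 for protein-coding genes, range 3 (without WT replicate 3 or mutant replicate 2) to 10 (without WT replicate 1). In E11.5 FL (7) they were 1 with an estimated correlation, 18 with no filter, range 4 (without WT replicate 3) to 10. In E11.5 HL (5) they were 0 with an estimated correlation, range 5 to 9 (without WT replicate 1). Of lists after rescaling, 132 results under other settings and 108 with 1 library left out kept their call, and 43 and 24 lost it.

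For the difference between limbs at E10.5 (2), the count was 1 with a pseudocount of 0.1, 0 with no filter, 0 rescaled, 5 with the block, 0 for protein-coding genes, range 2 to 5. At E11.5 (3) it was 1 rescaled, 1 with all 24 libraries, 1 for protein-coding genes, range 1 (without HL WT replicate 3) to 5763 (without HL WT replicate 1). For that between stages in FL (3) it was 18 with no filter, 7 rescaled, range 3 to 17 (without E10.5 mutant replicate 2). In HL (1) it was 3 with no filter, 3 with the block, 0 for protein-coding genes, range 1 to 5.

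For HL against FL in E10.5 WT (15), the count was 5 with no filter, 47 with all 24 libraries, 46 with the block, range 5 to 19. In E10.5 mutants (6), the only groups whose numbers pair by the residuals, it was 2 with no filter, 27 with all 24 libraries, 24 with the block, range 4 to 3297 (without HL replicate 3). In E11.5 WT (16) it was 8 with all 24 libraries. In E11.5 mutants (5140) it was 107 with no filter, 43 rescaled, 21 with all 24 libraries, 72 with the block, 63 for protein-coding genes, range 26 (without FL replicate 2) to 6457 (without FL replicate 1). Of FL and HL pairs with equal numbers 5 of 12 correlated over 0.1 (-0.357 to 0.37), and of WT and mutant pairs 3 of 12 (-0.191 to 0.294). For stage in WT, the count was 4765 rescaled in FL (2723), range 1206 to 2755, and in HL (4281) the range was 2577 to 4177.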

Other observations

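In this part the tests chosen only after the result was seen were those of structural RNA and genotype for the E11.5 FL shift, those of structural RNA and of chromosome 7 for Capns1, the other settings for minor-intron genes and the splits after rescaling.

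Genes listed by hand as having minor introns were over-represented among the E11.5 FL falls after rescaling. Of 71 listed genes 6 were among 131 falls of 10978 genes, and 0 were among the rises. The odds ratio was 7.96 (2.77 to 18.8, Fisher's exact test, two-sided, p = 0.000195). That test takes genes as independent, while camera with an estimated correlation gave this list adjusted p = 0.723. On the deposited scale, where most genes are shifted up, 0 of 42 falls were in the list (Fisher's exact test p = 1), and with protein-coding genes summed anew 2 of 55 were (odds ratio 5.84, Fisher's exact test p = 0.0503). With 1 library left out the odds ratio was 4.56 to 22.6 (Fisher's exact test p up to 0.0165), but on 2 falls alone (Spc24 and Kifap3) without WT replicate 2, WT replicate 3 or mutant replicate 2. The fallers include genes of the kinetochore (Spc24), kinesin transport (Kifap3), cilia (Ift80), mRNA export (Thoc2) and RNA polymerase II (Polr2e). Outside chromosome 7, genes lower in both E11.5 limbs at an unadjusted limma p under 0.01 were, besides Rnu11 and the overlapping Gm28872, Fbxo44 (-0.73 in FL, -0.77 in HL), the histone deubiquitinase gene Mysm1 (-0.69, -0.32), Slc22a17 (-0.47, -0.49), Stxbp6 (-0.41, -0.40), Zfp286 (-0.40, -0.30) and Smim20 (-0.30, -0.30). Shh was between 0 and 1.33 TPM in all 24 libraries, too low for a comparison here.

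Most genes were higher in mutant E11.5 FL on the deposited scale (median 0.39). Summing the protein-coding genes anew brought the median to 0.0502, but that takes out any uniform shift of those genes whatever its cause (a rise of 0.393 added to the mutant libraries also gave 0.0502). A smaller share of structural RNA and a rise of most genes thus cannot be told apart here, since TPM keep no absolute amounts. Whether genotype changed that share cannot be told apart from the preparation of the libraries: the difference of 5.62 points in protein-coding share had an exact permutation p = 0.1, the smallest that 3 against 3 allow. An effect of U11 loss on structural RNA thus stays open and untested.

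After rescaling Capns1 and its neighbour Tbcb were lower in mutants of both limbs and stages, at E11.5 least so in the Xist-positive replicate 3 (Capns1 16.5 in both limbs, against 7.51 to 11 in the other mutants and at least 21.9 in WT). Capns1 passed only in E10.5 FL (-0.75 ± 0.09, adjusted p = 0.03), where the call was lost in all 6 leave-outs (up to 0.276). A change in the share of structural RNA moves the TPM of all other genes by a common factor, which rescaling takes out. With protein-coding genes summed anew Capns1 stood at -0.787 ± 0.138 in E10.5 FL (adjusted p = 0.198) and -0.612 ± 0.138 in E10.5 HL. At E11.5 it stood at -0.996 ± 0.258 in FL and -1.233 ± 0.258 in HL. Tbcb stood at -0.451, -0.505, -0.693 and -1.039, and the medians of all genes at -0.03, 0.02, 0.05 and -0.08. Capns1 and Tbcb thus lay below the median of all genes in each comparison, though none passed the threshold. Since rescaling had removed such a shift before, summing anew was bound to give a like outcome. It adds no support for or against that share. Genes within 1 Mb cannot be told apart from other windows. Of 44 neighbours 30 were lower, with a median of -0.0696, at percentile 8.02 of 9095 windows. Alkbh6 and Zfp420, among the 16 genes below, lie in that window. Of the 16 genes with an unadjusted p under 0.01 in both E11.5 limbs, 8 lie on chromosome 7 (755 of 10642 tested; odds ratio 13.2), and 4 of 12 outside that window (odds ratio 7), but the first set holds Rpl28, Capns1 and Tbcb, and the second Rpl28, the genes that led to the question, so neither decides. Without these and the window 3 of 11 remain (odds ratio 5.25, 0.896 to 21.9, Fisher's exact test p = 0.0327), few genes with an interval that includes 1. A chromosome 7 segment of another strain, carried with the Cre allele, could give this, as could loss of U11 itself; no variant data were used here, and either reading stays a hypothesis. Rpl28, the lowest of these genes at E11.5, showed no like fall in replicates 1 and 2 at E10.5. There it was 69.3 to 91.2 rescaled TPM in mutants against 65.0 to 90.0 in WT. Replicate 3 was at 200.3 to 386 in all 4 groups, WT included. As deposited, the replicate 3 mutants were lower than WT, at 136.3 against 303.7 TPM in FL and 165.3 against 427.3 TPM in HL. Neither reading was tested on these levels of Rpl28. The difference of its effect between stages did not pass (adjusted p = 0.281 in FL and 1 in HL). That fit has no term for the replicate number, so the level of replicate 3 widens its spread. Not passing thus does not show like effects at both stages, and what sets Rpl28 stays open.

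The numbers of genes and lists past the threshold were compared with other splits of the same libraries. Where 3 are set against 3 there are 10 splits, too few for a share under 0.05. For mutant against WT on the deposited scale, 2 splits in E10.5 FL gave as many genes (3 called; highest other 3), 6 in E10.5 HL (1; 2), 1 in E11.5 FL (3733; 3) and 1 in E11.5 HL (4; 3). After rescaling they were 1 in E10.5 FL (3; 2), 3 in E10.5 HL (1; 2), 1 in E11.5 FL (183; 2) and 4 in E11.5 HL (2; 2). For lists they were 6 in E10.5 FL (9; 11), 9 in E10.5 HL (5; 14), 5 in E11.5 FL (7; 14) and 10 in E11.5 HL (5; 13). For HL against FL they were 1 in E10.5 WT (15; 9), 3 in E10.5 mutants (6; 8046), 2 in E11.5 WT (16; 3538) and 1 in E11.5 mutants (5140; 4), and for stage in WT 1 in FL (2723; 0) and 1 in HL (4281; 1). The splits with 8046 and 3538 genes point to a structure of the samples in scale: in them the median of all genes was -0.706 and 0.304, and after rescaling each called 1 gene. The surplus of lists goes with the preset correlation: with an estimated one the real split and the highest other gave 0 and 1 lists in E10.5 FL, 2 and 1 in E10.5 HL, 1 and 1 in E11.5 FL and 0 and 2 in E11.5 HL.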
